A study of Mus musculus with 18 samples.

How the data were processed

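Tail DNA of 9 mice (1 sire, 1 dam, 7 progeny) and of 1 reference male was compared on 18 Agilent oligonucleotide arrays, 2 per mouse with exchanged dyes, per the labels. The arrays were scanned and quantified with Agilent Feature Extraction 12.1.0.3, per the file headers, on a custom design with probe positions on mm9. The deposited red and green processed signals are intensity values, background-subtracted with spatial detrending and put on one scale by linear dye normalization, per the file headers. The median spot and median background columns, also deposited, are intensity values without normalization. The deposited log ratio is a log10 value of red over green processed signal, per the file headers. The deposited table of the whole series holds log2 values, and the tool that made it is not given in the sources used here. Set against the scanner values, its columns correlated with red over green at 0.991 to 1.00 where the mouse was in Cy3 and at -0.995 to -0.984 where it was in Cy5. These log2 values deposited by the authors are thus reference over mouse on both orientations, opposite to the direction used here. Their column medians were 0.0138 and -0.00111 in the sire, 0.0136 and -0.00051 in the dam, and between -0.00384 and 0.0194 over all arrays. Whether they were centred or corrected further stays unknown.

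Of the 973116 features of an array, control features were left out, which left 966371. Features that Feature Extraction marked as non-uniform or population outliers in either channel were left out on that array, between 126 and 5480 per array. No feature was saturated. Features of 1 probe were averaged, which gave 950749 probes, of which 950622 were autosomal, 68 on X, 23 on Y and 36 on unplaced sequence. Log2 of red over green processed signal was centred on the autosomal median of each array, with no loess or quantile step, turned to mouse over reference by the dyes in the labels, and averaged over both orientations as 1 value per mouse. Between different mice in the same orientation, arrays correlated over probes at 0.142 to 0.631 with the mouse in Cy5 and at 0.203 to 0.535 with the mouse in Cy3, so none ran against the others. The 2 orientations of 1 mouse, once turned, correlated between -0.435 and 0.219, and probe effects that follow the dye cancel in their average. Median processed signals lay between 982.5 and 1016 in red and between 990.4 and 1016 in green. The median raw spot signal lay between 170.0 and 430.0 in red over a background of 27 to 31, and 99.3% of features were well above background in both channels of every array.

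Copy number calls were made per mouse on the autosomes with a caller written for this work after the aberration score used with such arrays. A call was a run of 3 to 1000 consecutive probes whose summed log2 value, divided by the noise and the square root of the number of probes, was at least 6 in size. Calls were taken in order of that score without overlap. A call was kept where its mean was at least 0.25 from 0 with the same sign in both orientations. The noise came from the spread of differences between neighbouring probes. Overlapping calls of different mice were merged into regions, and the value of a region in each mouse is its mean over the probes of the strongest call. Regions were put in 4 classes: all 9 mice, a parent and some progeny, a parent only, and progeny only. A progeny-only region differed from both parents where a calling pup lay at least 0.25 beyond the sire and the dam in both orientations. Expected false calls came from the same caller run on the dye-following signal, in which each orientation had its mean over mice removed and was then combined so that a difference of the mouse cancels. The caller was tested on simulated data, with steps of 3, 5, 10, 30 and 100 probes added to that signal. X and Y probes were too sparse for the caller and were used only for direction and sex.

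Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on 1 value per mouse, over the 943743 autosomal probes measured in all 9 mice, against a Benjamini-Hochberg threshold of 0.05. One fit tested the mean of the 9 mice against 0, the other the 7 progeny against the 2 parents. The test was run on simulated data with 200 changed probes among 100000, and it found 100% of those raised by 0.5 in all mice. The simulated values held only independent noise of the size seen between neighbouring probes, with no other difference between mice. Each of the 5 scan days held mice of either the parents or the progeny, so the day was tried as a random block (duplicateCorrelation). Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and numba 0.67.0.

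Regions were named by a rule fixed before the data were examined: the 10 with the largest score in each class, for progeny-only regions among those that differed from both parents, and the 10 probes of largest change per direction. Regions and probes are given by position, since the gene table at hand is on another build, and no gene was named from a position. For the same reason the tests of 17 gene lists, planned before the data were examined, were not run. The alternatives were normexp background correction (offset 50, on median signals, since the mean signals it was planned on are not used here), loess, a running median over 500 probes subtracted, only probes well above background, 1 dye orientation alone, the deposited log2 table, other thresholds of the caller, a minimum overlap of 50%, each mouse left out in turn, and the scan day as a block. A median rule, a minimum of 10 probes, the median over the 9 mice removed and the removal of progeny 3, 4 and 7 were added after seeing the data. The later arrays and copy number assays that the study describes are not analysed here, nor are the families of irradiated sires.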

Results

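The series screened tail DNA of 1 mouse family for copy number differences with a 2-colour genomic array. The family belonged to the arm whose sire was not irradiated, in a study that asked whether continuous gamma irradiation of male mice at 0.05 mGy per day for 400 days leaves copy number changes in their progeny. DNA came from 1 sire, 1 dam and 7 progeny of the strain C57BL/6JNrs. Each mouse was hybridised against DNA of 1 reference male from the same colony, on 2 arrays with the dyes exchanged, which gave 18 arrays. Values below are log2 of mouse over reference, averaged over both dye orientations, and positions are on the mouse build mm9. Each mouse is 1 animal, so the 2 arrays of a mouse are technical repeats, and a call in 1 mouse carries no p-value. Each array held 973116 features, and the autosomes were covered by 950622 distinct probes at a median spacing of 2053 bp. The probe-to-probe noise of a single array lay between 0.136 and 0.215, and that of the average of both orientations between 0.0724 in progeny 2 and 0.147 in progeny 3. The number of arrays and this noise limited the precision. In a test with known steps, every added step of -1, -0.58 or 0.58 was found in every mouse from 3 probes up, and 47.8% of 3-probe steps of 0.3 were found. The steps were added to a signal with the mean over mice removed, so probe effects that follow the dye in all mice were absent. The share found in the real data may therefore be lower.

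The 68 X probes and 23 Y probes showed the direction of the ratios and the sex of each animal. The X probes had a median of 0.95 in the dam, 0.96 in progeny 3, 0.98 in progeny 4, 0.97 in progeny 6 and 0.96 in progeny 7. The Y probes had medians of -2.27, -2.54, -2.24, -2.08 and -2.55 in the same 5 mice. In the sire and in progeny 1, 2 and 5, the X medians lay between -0.0071 and 0.016 and the Y medians between -0.019 and 0.013. The labelled dam therefore had the X and Y values of a female against a male reference in both dye orientations, with X medians of 0.93 with the mouse in Cy5 and 0.92 with the mouse in Cy3.

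The first comparison asked which regions differed from the reference in the whole family. The strongest region of the genome lay on chromosome 14, positions 53424661 to 54386805, spanned 962 kb and held 104 probes. It was lower than the reference in both parents and in 6 of the 7 progeny, with a mean of -0.48 ± 0.030 (SD, n = 8 mice) and a range of -0.52 to -0.44. Progeny 5 was the exception, with a mean of 0.029, near the level of the reference itself. Of its 104 probes, 91 lay within 0.25 of 0. Its probes at 53987431, 54174556 and 54058301 lay at 1.32, 0.87 and 0.80, and its lowest, at 54298700, at -0.37. The median probe of the 8 mice lay at -0.54, close to the -0.58 of 2 copies against 3, but the probes were uneven. In the mean of the 8 mice 86 of the 104 lay below -0.25, 18 did not, and 7 lay below -0.75. These 7 lay between positions 53673489 and 54304484, mostly close together. Consecutive probes at 53714075, 53716349, 53718830 and 53759005 lay at -0.950, -0.984, -0.953 and -0.998, with SDs over the 8 mice of 0.0405 to 0.125. The probe at 53673489 lay at -0.987, and those at 53994847 and 54304425 at -0.802 and -0.760. Whether the consecutive probes form a stretch with its own copy number was not tested. The region was lower in each dye orientation, for example at -0.54 and -0.48 in the dam. With progeny 5 at the reference level, 0 regions were called in all 9 mice, and without progeny 5 the chromosome 14 region was the 1 called in all 8 others.

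**Figure D1:**
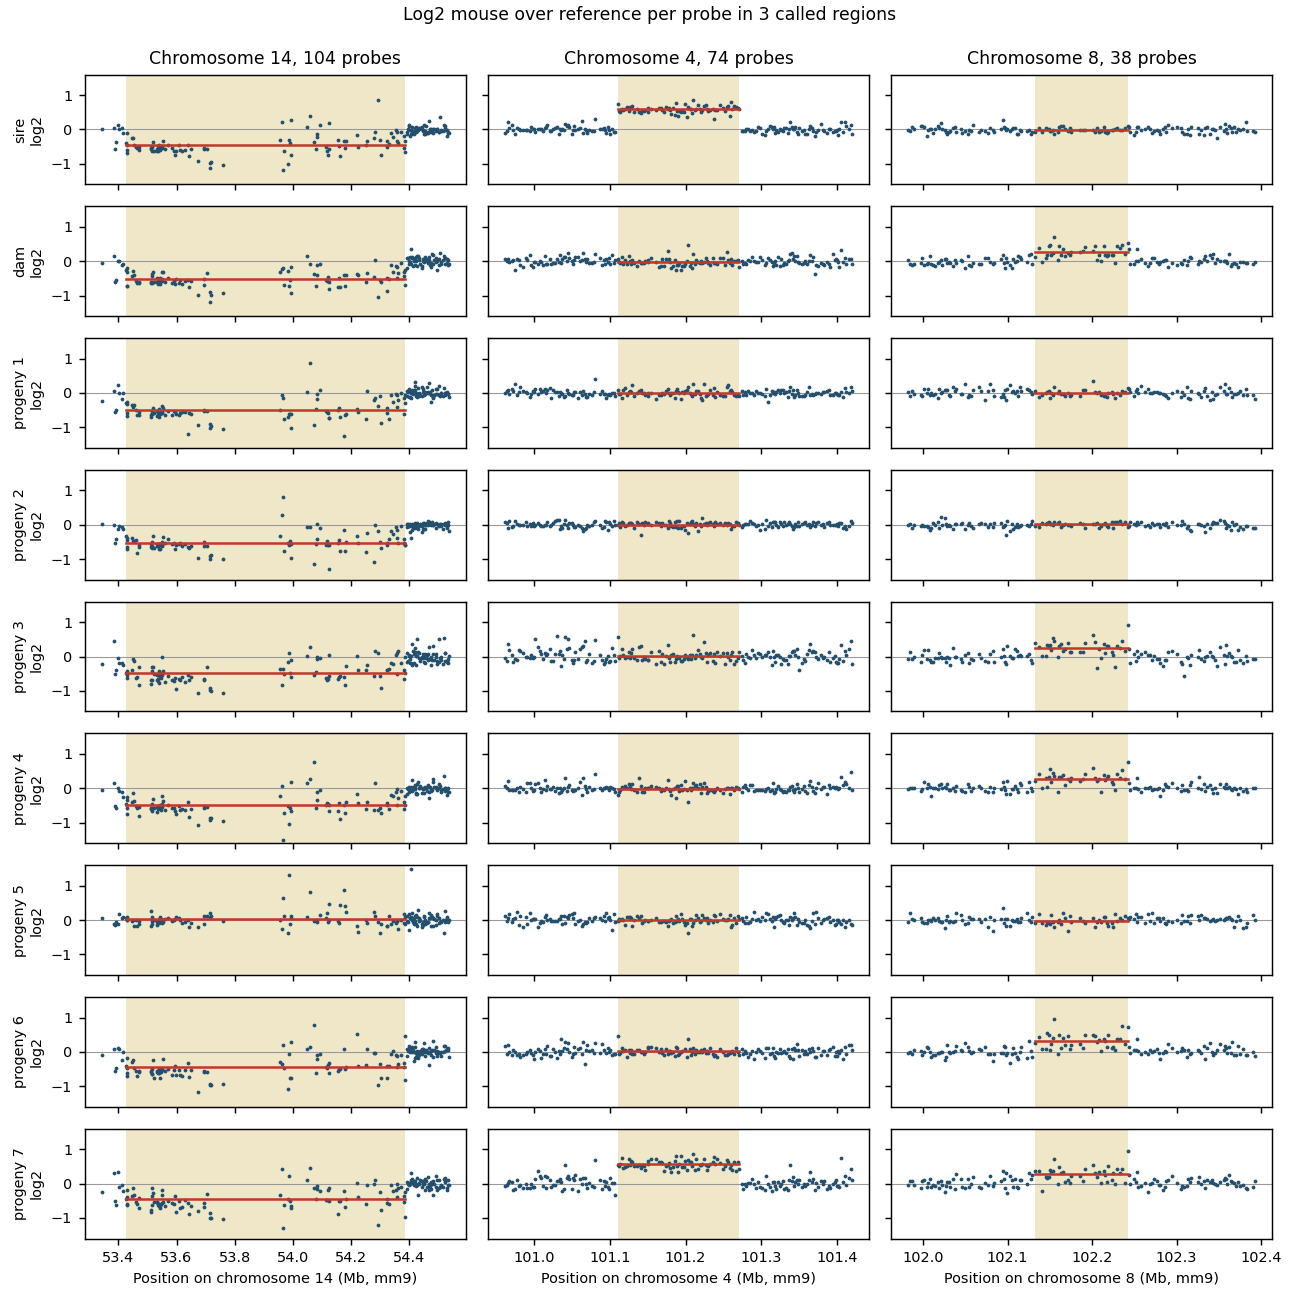
Log2 of mouse over reference (vertical axis, values beyond 1.5 drawn at 1.5) of each probe against its position in Mb on mm9 (horizontal axis), for 9 mice in rows and 3 called regions in columns, with 150 kb on either side. The shaded span is the strongest call, and the red line is the mean of a mouse over it: on chromosome 14 progeny 5 lies at 0.029 and the other 8 mice between -0.52 and -0.44, on chromosome 4 the sire lies at 0.58 and progeny 7 at 0.56, and on chromosome 8 the dam and progeny 3, 4, 6 and 7 lie between 0.24 and 0.31.

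The second comparison asked which differences a parent shared with part of the progeny, as a transmitted copy number would be. The clearest was a gain on chromosome 4, positions 101110482 to 101270535, of 74 probes over 160.1 kb. The sire lay at 0.58 ± 0.095 and progeny 7 at 0.56 ± 0.12 (SD over 74 probes), and all 74 probes were above 0 in both. This was the level of 3 copies against 2, which is 0.58. The dam lay at -0.018, and the other 6 progeny lay between -0.011 and 0.023. The gain was therefore seen in the sire and in 1 of 7 progeny, with 0.54 and 0.59 in the 2 orientations of progeny 7.

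A second set of shared regions followed the X and Y probes. On chromosome 3, positions 25417435 to 25432738, 3 probes lay at -1.66 in the dam, -1.79 in progeny 3, -1.69 in progeny 4 and -1.61 in both progeny 6 and progeny 7, and between -0.039 and 0.065 in the other 4 mice. On chromosome 8, positions 102132083 to 102242602, 38 probes over 111 kb lay at 0.26 in the dam and at 0.24, 0.28, 0.31 and 0.27 in progeny 3, 4, 6 and 7, against -0.025 to 0.010 in the other 4. Calls of 3 probes gave the same split as losses on chromosome 9 at 35857910, on chromosome 5 at 123596881 and on chromosome 11 at 112961382. Their 3-probe means in the dam were -0.67, -0.71 and -0.63. In the strongest mouse of each, 1 probe carried the value. It lay at -2.41 in progeny 6 on chromosome 9, at -2.09 in the dam on chromosome 5 (position 123598779) and at -2.05 in progeny 4 on chromosome 11. In these 5 regions the mice away from 0 were those with X medians of 0.95 to 0.98. On chromosome 13, 1 probe at 95707465 lay at 2.14 in the sire, 0.19 in the dam, between 1.31 and 2.11 in 6 progeny, and at -0.012 in progeny 5.

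**Figure D2:**
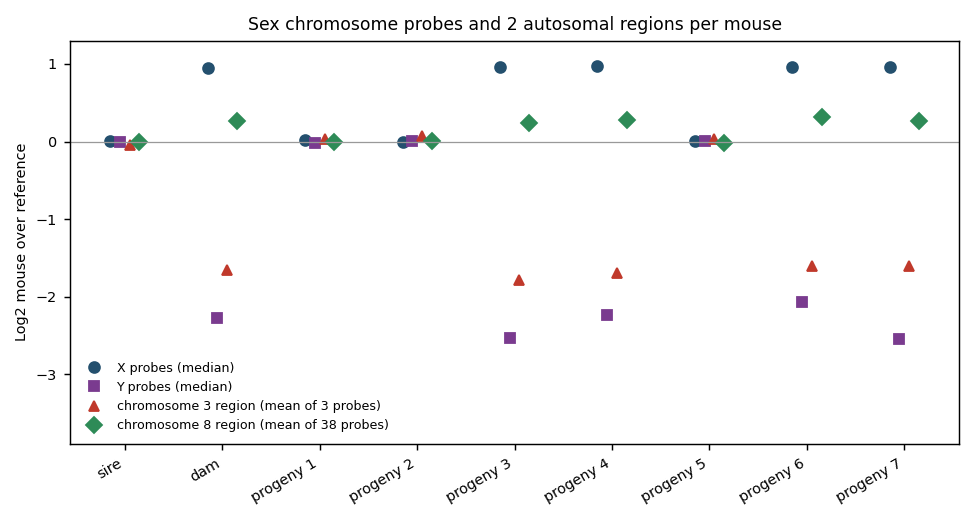
Log2 of mouse over reference (vertical axis) for each of the 9 mice (horizontal axis): the median of the X probes, the median of the Y probes, the mean of the 3 probes on chromosome 3 and the mean of the 38 probes on chromosome 8. The chromosome 3 values lie between -1.79 and -1.61, and the chromosome 8 values between 0.24 and 0.31, in the 5 mice with X medians of 0.95 to 0.98.

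Altogether 28 regions were called in a parent and some progeny, where the same caller found 9 in the part of the signal that follows the dye and not the mouse. That signal has the mean over mice removed, so effects that mice share are left out of the 9. Of the 10 shared regions with the largest scores, 5 had a median over their probes at least 0.25 from 0 in their strongest mouse, and the other 5 rested on 1 probe. The remaining 2 of the 10, on chromosome 4 at 137854898 and on chromosome 12 at 36142919, were gains of 0.69 and 0.68 in the dam. On chromosome 4 the gain was 0.20 without its largest probe, 0.20 among probes well above background on every array and 0.062 with normexp background correction. On chromosome 12 the mean without its largest probe was -0.022, and the gain turned to -0.022 among probes well above background on every array. Without the dam, 7 shared regions were left.

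The next class held regions called in a parent and in none of the progeny. There were 65 such regions, 50 in the dam, 14 in the sire and 1 in both, against 10 in the dye-following signal, which has the mean over mice removed. The largest score was that of a loss on chromosome 1, positions 106041489 to 106053286, at -0.54 in the sire, where 1 probe carried the value and the mean without it was -0.039. A call in both parents, on chromosome 11 at 16966751, lay at -0.41 in the sire and -0.35 in the dam, with progeny 7 and progeny 5, not called, at -0.34 and -0.23, and the sire's value was -0.097 with normexp and -0.16 among probes well above background. Of the 10 regions named by score, the one with the most probes had 5, on chromosome 5 from 87149535 to 87158898, at 0.31 in the dam, 0.088 with normexp and 0.22 with loess, and at 0.25 in progeny 7, which was not called. Uncalled progeny lay near the calling parent in 3 more of the 10: on chromosome 5 at 135872392 progeny 3 at 0.35 and the sire at 0.37, on chromosome 4 at 52558199 progeny 7 at 0.33 and the dam at 0.36, and on chromosome 5 at 64185563 progeny 3 at 0.33 and the dam at 0.39. Without the dam 15 such regions were left, and with a minimum of 10 probes, a setting added after seeing the data, there were 0.

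The comparison at the centre of the design asked which regions were called in the progeny and in neither parent. There were 1000 such regions, mostly short gains, and 506 of them differed from both parents by at least 0.25 in both orientations. With normexp these counts were 292 and 163. Gains were 90.7% of all calls in the main setting, 84.5% with normexp, 90.3% with the mouse in Cy5 alone and 38.6% with the mouse in Cy3 alone. A single orientation keeps probe effects that follow the dye. The progeny-only regions were spread unevenly: 849 involved progeny 3, 4 or 7, and 151 did not. Progeny 3 and 4 were the only mice of 1 scan day and progeny 7 the only mouse of another, so scan day and mouse cannot be told apart for this excess. Per mouse, the caller gave 375 calls in progeny 3, 288 in progeny 4 and 447 in progeny 7, against 50, 11, 65 and 70 in progeny 1, 2, 5 and 6, 22 in the sire and 74 in the dam. The noise of the dye-averaged values was highest in progeny 3 and 7, at 0.147 and 0.130. It was 0.0941 in progeny 4 and between 0.0724 and 0.104 in the other mice. Gains made up 367, 272 and 430 of the calls in progeny 3, 4 and 7. The dye-following signal gave 16, 6 and 33 calls in those 3 mice and 132 progeny-only regions in all, but that signal has the mean over mice removed. With the median over the 9 mice removed from each probe, a choice made after seeing the data, progeny 3, 4 and 7 had 193, 30 and 213 calls, progeny 1, 2, 5 and 6 had 49, 32, 106 and 61, and the sire and dam 18 and 47.

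**Figure D3:**
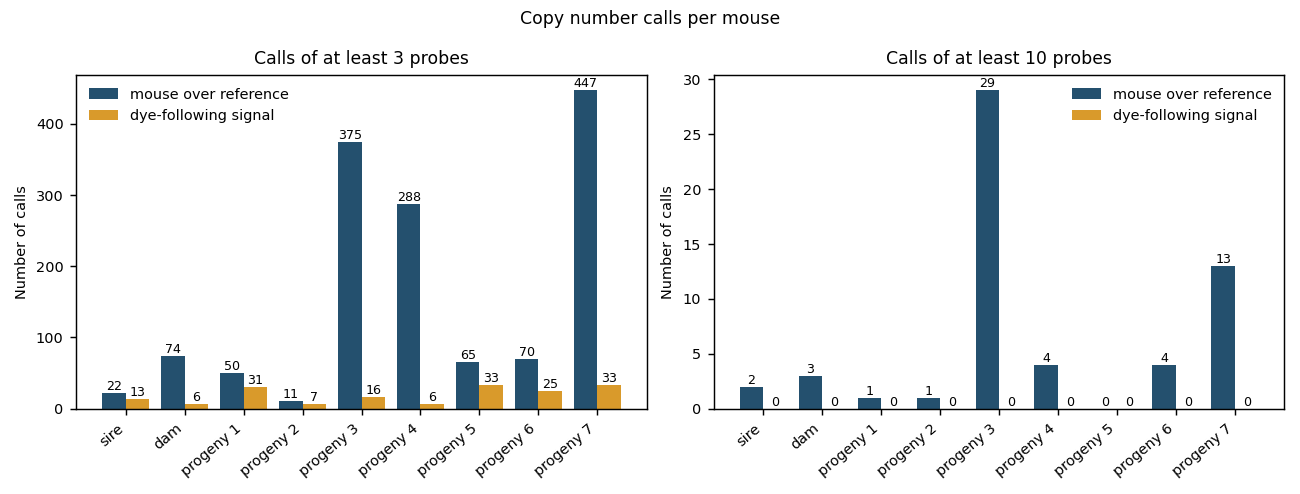
Number of calls (vertical axes, from 0) in each of the 9 mice (horizontal axes) for calls of at least 3 probes on the left and at least 10 probes on the right, in mouse over reference and in the dye-following signal. Progeny 3, 4 and 7 have 375, 288 and 447 calls of at least 3 probes, and no mouse has a dye-following call of at least 10 probes.

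Of the 10 progeny-only regions named by score, 5 lay less than 0.25 from 0 without their largest probe. A gain on chromosome 4, positions 70119554 to 70122398, lay at 1.35 in progeny 5, where 1 probe read 7.20 with the mouse in Cy5 and 0.69 with the mouse in Cy3, and the mean without it was 0.055. A loss on chromosome 6 at 10774302 lay at -1.12 in progeny 5, with 1 probe at -0.45 and -5.95 in the 2 orientations, and progeny 7, not called, at -0.82. Losses of 3 probes on chromosome 15 at 33312301 in progeny 2 and on chromosome 9 at 76921448 in progeny 1 lay at -0.56 and -0.66, and at -0.0077 and -0.0047 without their largest probe. A loss of -0.59 on chromosome 7 at 47256006 in progeny 1 and a gain of 0.72 on chromosome 3 at 80632611 in progeny 6 lay at -0.42 and 0.54 without their largest probe and at -0.059 and 0.22 with normexp. Progeny 6 and 7, not called on chromosome 7, lay there at -0.39 and -0.36, and progeny 7, not called on chromosome 3, at 0.52. On chromosome 19 at 46797398 progeny 3, 4 and 7 lay at 0.96, 0.68 and 0.76, progeny 1 at 0.36, and the sire and dam, not called, at 0.22 and 0.31. Progeny 6, not called, lay there at 0.33. In progeny 4, which had the highest score, the gain was 0.56 without its largest probe and 0.85 with normexp. On chromosome 8 at 111744106 and on chromosome 19 at 56887926, progeny 3, 4, 6 and 7 were called, at 0.94, 0.37, 0.42 and 0.69 on chromosome 8, where the dam lay at 0.21, and at 0.93, 0.33, 0.28 and 0.47 on chromosome 19, where the dam lay at 0.030. Without the largest probe progeny 3 lay at 0.29 and 0.050, and with normexp at 0.11 and 0.13. The progeny called in these regions were those with X medians of 0.96 to 0.98. On chromosome 8 the dam also lay above the sire, at 0.044, and above progeny 1, 2 and 5, at -0.18, 0.015 and -0.21. On chromosome 19 the dam lay below the sire, at 0.063, and below progeny 1 and 2, at 0.19 and 0.14, with progeny 5 at -0.14. The widest of the 10 named regions had 13 probes, on chromosome 4 from 142988304 to 143017099, at 0.44 in progeny 3, where it was 0.12 with normexp, and 0.17 in progeny 7. Of the 10 named regions, 4 had a median over probes of at least 0.25 from 0. Without progeny 3, 269 regions differed from both parents, and without progeny 3, 4 and 7 together, a choice made after seeing the data, 46 did.

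Single probes were then tested over mice. Against the reference, 2609 of 943743 autosomal probes passed in limma with Benjamini-Hochberg adjustment, 2277 higher and 332 lower in the 9 mice. The 10 lowest all lay in the chromosome 14 region, which held 78 of the 2609 probes. The lowest was the probe at 53673489, at -0.90 ± 0.076 (SE, limma adjusted p = 0.00214), below 0 in 9 of 9 mice. The highest was the chromosome 13 probe at 95707465, at 1.31 ± 0.20 (SE, limma adjusted p = 0.0340), above 0 in 8 of 9 mice. Without the sire, the dam or progeny 1, 3, 4, 6 or 7, the largest passing change was at most 0.91 in size. The chromosome 13 probe thus no longer passed in those runs. The next highest were probes on chromosome 7 at 137374833, chromosome 4 at 122494594 and chromosome 18 at 49324618, at 0.76, 0.70 and 0.70. The higher probes had a median change of 0.24, and 99.4% of them lay below the 0.58 of 1 added copy, with per-mouse medians from 0.071 in progeny 5 to 0.41 in progeny 7. The reference was 1 animal, so the test left out its own spread, and the 9 mice were relatives. The balance of directions depended on the mice: higher and lower probes numbered 51 and 52 without the sire, 15 and 43 without the dam, 14 and 48 without progeny 1, 2392 and 267 without progeny 2, 150 and 87 without progeny 3, 9 and 42 without progeny 4, 16253 and 2234 without progeny 5, 40 and 50 without progeny 6, and 89 and 63 without progeny 7. The count ran from 51 without progeny 4 to 18487 without progeny 5, and it was 668 with the scan day as a random block.

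Progeny against parents, 0 of the 943743 probes passed in limma with Benjamini-Hochberg adjustment, and 22573 had an unadjusted p under 0.05, fewer than the 47187 that a test without any difference gives on average. In simulated values, limma found 96% of 200 probes raised by 0.5 in the progeny among 100000. Those values held only independent noise of the size seen between neighbouring probes, and fewer probes were adjusted for than the 943743. The share found in the real data may therefore be lower. Sire and dam formed 1 group of 2, so a region that 1 parent or 1 of the progeny carried, such as the chromosome 4 gain, stayed outside what this test could call. Both parents were scanned on 1 day and the progeny on 4 other days, and the count was 0 with the scan day as a random block. Without the dam 21 probes passed and without the sire 1, where the lone parent is assumed to vary like the progeny.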

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

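Of the tests weighed here, only the loess test of the short gains was set before its result was seen; the others were chosen after the values were seen. Among the 7 progeny, 39 sets of values were checked for a mouse far from the others, and 8 had one, where chance gives about 1 in 20. The 30 named regions were picked for large values, so some such mice follow from the choice.

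Progeny 5 stood apart on chromosome 14 at 53424661, at 0.029 against -0.52 to -0.44 in the other 6 progeny. It also stood apart on chromosome 13 at 95703166, at -0.020 against 0.44 to 0.76, and at the single probe behind that call, at -0.012 against 1.31 to 2.11. DNA of the reference male or of an unrelated male of the colony on the arrays of progeny 5 may account for both loci, since the chromosome 13 probe lay at -0.012 there. The number of calls does not settle it: progeny 5 had 65 calls against 33 in its dye-following signal, 15 against 8 with at least 5 probes, and 5 against 7 under the median rule. A new gain in progeny 5 stays open too: the dam lay only 0.20 above progeny 5 at the chromosome 13 probe, so a pup that took the other copy from the sire would look the same there. Only these explanations were weighed, and inheritance of different copy numbers from the parents on chromosome 14 was not tested. The X and Y probes do not decide, as any male gives values near 0 against a male reference, and a genotype of progeny 5 would be needed.

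Short gains in progeny 3, 4 and 7 made up most progeny-only regions. Of their 1069 gain calls, 65.9% remained after loess, which argues against an intensity-dependent bias as the whole cause, though it may account for part. Under the median rule 72.5% remained in progeny 3 and 60.7% in progeny 7, which argues against single outlying spots as the whole cause in these 2. In progeny 4 the share was 43.8%, but its gains had a median level of 0.359, against 0.538 in progeny 3 and 0.479 in progeny 7. Its gains thus lay closer to the threshold of the rule, so this share cannot decide on single spots there. With the median over the 9 mice removed, 11 of the 272 gain calls of progeny 4 remained. Spots outlying in progeny 4 alone would mostly stay, so this argues against them as the cause of most of its calls. With normexp 150 of the 1069 remained, and 73.1% of the probes in these calls had a signal over background below the median of all autosomal probes. Background at dim probes is thus a candidate explanation, although calls that chance makes would also gather at noisy dim probes. The scan day cannot be told apart from a property of these 3 mice, since 0 other mice were scanned on their days. The sire, where not called itself, lay above 0 in 92.5% of these calls, and the dam in 94.5%. Of all single autosomal probes, 49.1% and 48.6% lay above 0 in the sire and dam. A call is a mean over 3 or more probes, so these shares have unlike units, and the probes were not matched for signal. A whole copy gained in the calling pup alone would leave the parents at 0, so the parents argue against it for the set, although the levels alone, with quartiles of 0.39 and 0.54, would not. A probe bias shared by most mice and larger in these 3 is consistent with the values, with progeny 5 above 0 in 29.7% and progeny 2 in 63.3% as exceptions. With the median over the 9 mice removed, 150 of 367, 11 of 272 and 155 of 430 gain calls remained in progeny 3, 4 and 7, so a bias of equal size in all mice would not cover progeny 3 and 7, and single true gains among them cannot be excluded.

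Regions shared by the dam and progeny 3, 4, 6 and 7 formed another pattern. Over 943743 autosomal probes, 20 separated the 5 mice with X medians above 0.5 from the other 4 by at least 0.25 in both orientations. Of the 126 splits of the 9 mice into 5 and 4, none of the others separated more than 9 probes. The split was taken up after called regions had shown it, and the probes of those regions were not left out. The count therefore partly restates the pattern. Sequence that the X or Y chromosome also holds may account for these 20. Of the 28 regions called in a parent and some progeny, 5 separated the same mice by at least 0.25, on chromosomes 3, 5, 6, 9 and 11. That they lay on 5 chromosomes argues against autosomal variants that the dam passed to the same 4 progeny as the cause of the set. In the chromosome 6 region, at 104238274, progeny 7 was not called and lay at -0.34. The chromosome 8 region was not among the 5, as progeny 3 lay at 0.24 and progeny 2 at 0.010. On chromosome 8 the highest of the 5 mice lay at 0.31, well below the 0.58 that the chromosome 4 gain reached on the same arrays, which argues against 3 copies in place of 2 of a single-copy stretch.

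The other values far from the remaining progeny are given without explanation. On chromosome 4 at 101110482, progeny 7 lay at 0.56 against -0.011 to 0.023. On chromosome 4 at 137854898, progeny 6 lay at 0.53 against -0.0083 to 0.21. On chromosome 4 at 52558199, progeny 7 lay at 0.33 against -0.061 to 0.11. On chromosome 4 at 70119554, progeny 5 lay at 1.35 against -0.055 to 0.098. On chromosome 4 at 142988304, progeny 3 lay at 0.44 against -0.010 to 0.17.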

How the results depend on the processing

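The counts depended strongly on the processing, while the chromosome 14 region, the chromosome 4 gain at 101110482 and the chromosome 8 region did not: in the mouse of their strongest call, other signal settings moved them by less than 0.05. Under normexp each of these regions still moved by more than the spread of its 2 orientations, the stricter measure used next. Of 150 values of the 30 named regions under other signal settings, 97 moved by less than the spread of the 2 orientations (values of 1 orientation alone do so by construction and are left out), 51 moved further with the same sign, and 2 changed sign, both on chromosome 12 at 36142919 in the dam (-0.0029 with normexp and -0.022 with only probes well above background). Counts follow in the order any mouse, all mice, parent and some progeny, parent only, progeny only, and progeny only that differ from both parents, where the main setting gave 1093, 0, 28, 65, 1000 and 506. Normexp gave 330, 0, 17, 21, 292 and 163. Loess gave 18 in a parent and some progeny and 43 in a parent only, with the other 4 counts within 1.5 times. Arrays with the mouse in Cy5 alone gave 890, 1, 31, 29, 829 and 808, and those with the mouse in Cy3 alone 1182, 1, 65, 62, 1054 and 1000. Gains were 90.7% of calls in the main setting, 84.5% with normexp, 86.6% with loess, 90.3% with the mouse in Cy5 alone and 38.6% with the mouse in Cy3 alone. The deposited table gave 1 in all mice and the other 5 counts within 1.5 times. A score of at least 8 gave 192, 0, 14, 5, 173 and 97, and one of at least 5 gave 2419, 0, 52, 105, 2262 and 889. At least 5 probes gave 360, 0, 14, 7, 339 and 131. A mean of at least 0.4 gave 503, 0, 12, 2, 489 and 92, and one of at least 0.15 gave 1584, 1, 49, 123, 1411 and 936. Of the settings chosen after seeing the data, the median rule gave 596, 0, 8, 22, 566 and 344, at least 10 probes gave 41, 0, 4, 0, 37 and 6, and leaving out progeny 3, 4 and 7 gave 271, 0, 13, 81, 177 and 46. Removing the median over the 9 mice gave 683 in any mouse, 618 in progeny only and 377 that differ from both parents. Subtracting the running median, keeping only probes well above background and asking for an overlap of 50% left all 6 counts within 1.5 times. With each mouse left out in turn, the counts ran from 810 to 1085, 0 to 1, 7 to 28, 15 to 72, 717 to 1021 and 269 to 704. Probes of all mice against the reference, 2609 in the main setting, numbered 6017 with normexp, 1589 with the running median subtracted, 381576 with the mouse in Cy5 alone, 343685 with the mouse in Cy3 alone, 668 with the scan day as a block, 1198 with a mean change of at least 0.25 as well, 2 without progeny 3, 4 and 7, and between 51 and 18487 with each mouse left out. The single-dye counts hold probe effects that follow the dye, by construction. Progeny against parents, 0 probes passed in every setting run, except between 0 and 21 with each mouse left out. The cause of the other changes was not tested. The gene list tests were not run, and no paired analysis was possible because the groups compared share no replicate numbers that pair mice. Although 99.3% of features were well above background on every array, keeping only such probes, which left 948 regions, took the chromosome 1 loss from -0.54 to -0.039 and the chromosome 19 gain at 56887926 from 0.93 to 0.050.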

Other observations

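Of the 8 regions with 10 or more probes in their strongest call, the 5 called in progeny only are given as values. On chromosome 14, positions 61798066 to 61819370, 13 probes lay at -0.28 in progeny 4, the 1 mouse called, and at -0.23, -0.24, -0.27 and -0.14 in the dam and progeny 3, 6 and 7, against 0.0022 to 0.058 in the other 4 mice. The dam and these progeny were the mice with X medians of 0.95 to 0.98. On chromosome 14 from 41740728 to 41772168, 18 probes lay at 0.35 in progeny 3 and 0.15 in progeny 4, the 2 mice called, and at 0.18 in progeny 7 and 0.10 in progeny 1. Progeny 3 was the 1 mouse called on chromosome 4 from 142988304 (13 probes), on chromosome 8 from 9269358 (12 probes, 0.30, with progeny 7 at 0.14) and on chromosome 4 from 89649116 (12 probes, 0.29, with progeny 7 at 0.19). Across autosomal probes, which are not independent replicates, the dye-averaged values of progeny 3 correlated with those of progeny 4 at 0.562 and of progeny 7 at 0.524, and those of progeny 5 with progeny 3 at -0.146.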
